A study of Mus musculus with 9 samples.

How the data were processed

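RNA of NIH-3T3 cells was measured on 9 Affymetrix whole-transcript arrays, 3 per group, 48 hours after transfection of a miR-378-3p mimic, a miR-378-3p inhibitor or a RISC-free control siRNA at 25 nM. Per the labels' protocols, total RNA was extracted with the Qiagen miRNeasy kit, amplified as cDNA and labelled with biotin. The authors deposited 1 log2 value per probe set and array. Partek 6.5 and RMA (robust multi-array average, which corrects background, normalizes quantiles of probes and summarizes probes by median polish) are named in the submitters' processing notes. The genome build behind the probe sets is not given in the sources used here, and the scanner files were not used here. The log base follows from RMA and from the range of the values, 2.64 to 12.5.

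The table held 28853 probe sets, with no missing value, and 0 sample columns were left unused. The platform annotation listed 21789 probe sets with 1 gene and 1621 with several, and left 5443 unnamed. Genes were named only from probe sets with 1 gene, and the probe set with the highest mean over the 9 arrays stood for a gene that had several, which was so for 998 of 19939 genes. Gene IDs of 19856 genes matched a RefSeq gene table (assembly GRCm38.p6, used for names only), and no symbol needed updating. Genes with a mean below the 40th percentile, 3.86 on the log2 scale, were left out, and 11963 genes were tested. The number of arrays limits the precision, and the median residual SD after moderation was 0.08. The labels call the samples triplicates without saying whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

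One linear model with a coefficient per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 4.37 prior degrees of freedom). The 3 comparisons were mimic with control, inhibitor with control and mimic with inhibitor. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Every adjusted p of a single gene comes from this limma test. Standard errors are the moderated ones of limma. Overlaps of the comparisons that share the control arrays were set beside 100 simulations of unchanged groups and beside the overlap of independent lists.

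Gene lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over 17 lists within a comparison, and again with the correlation estimated from the residuals. The lists were reported miR-378 targets, interferon-stimulated genes, DNA replication, mitosis, p53 targets, sterol synthesis and uptake, fatty acid synthesis and adipocyte genes, respiratory chain subunits, fatty acid oxidation, matrix and myofibroblast genes, unfolded protein and amino acid stress, glycolysis and hypoxia, small RNA machinery, immediate early genes, inflammatory genes, ribosomal proteins, and markers of macrophages, epithelium, endothelium and muscle. The reported targets were genes named in the literature for either arm of miR-378. Members not tested were on a probe set of several genes, unnamed or below the level filter, and are not analysed here.

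Genes are named by a rule. It takes, for each comparison with the control, the 12 largest falls and the 12 largest rises among genes past the threshold whose groups did not overlap. It also takes up to 10 genes for each combination of calls in both comparisons, ranked by the smaller fold change, up to 4 changed members of each list, every reported target and the host gene Ppargc1b. Samples, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were the level filter, quantile normalization, median centring, fits of 6 arrays, the replicate number as a block, moderation with trend, the mean of all probe sets, a fold of at least 1.5 and leaving out each array. Alternatives chosen after seeing the data were a fit without mimic 3 and inhibitor 1, both scalings for the gene lists, and an estimated correlation for the replication list after quantile normalization and without these 2 arrays.

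The planned search for seed sites of miR-378-3p and of other microRNAs, and the ranking of heptamers, needed transcript sequences and were not run. On simulated data in which 200 of 11963 genes changed, the mimic comparison recovered 47.8% of genes changed by 0.3 on the log2 scale, 79.1% of those changed by 0.5 and 98.5% of those changed by 1, with 9 false among 159 calls. The inhibitor comparison recovered 59.7%, 85.1% and 100%, with 9 false among 172 calls. In the same simulated data camera called the 1 list that was shifted and 0 of 16 others. Noise was drawn for each gene on its own there, so this tests neither the limma calls nor camera where genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.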

Results

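NIH-3T3 is a mouse embryonic fibroblast line. Its cells received a synthetic RNA that acts as miR-378-3p (the mimic), an RNA that blocks this microRNA (the inhibitor), or a control siRNA modified to stay out of the silencing complex. Each group had 3 arrays. The series title gives the aim as finding genes that miR-378-3p targets. The median over all probe sets lay between 3.94 and 4.03 (log2) on each of the 9 arrays, and the 75th percentile ran from 5.55 on mimic 3 to 5.76 on inhibitor 1. The first principal component of the genes tested held 60.5% of the variance. Mimic 3 (score -20.5) and inhibitor 1 (20.88) lay at its ends, with the controls between -4.38 and -2.78 and mimic 2 among them at -3.95. No pair of arrays shared more than 3.58% of its values, so none was a copy of another, and all 9 were used. This check cannot tell separate cultures from technical repeats.

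The first question was which transcripts fall when miR-378-3p is supplied. With the mimic, Dazap2 (gene ID 23994) and Zmpste24 (gene ID 230709), which encodes the protease that matures prelamin A, fell most among the named genes. Dazap2 stood at 7.92 ± 0.07 in the controls and at 6.61 ± 0.43 with the mimic (log2, SD, n = 3), a log2 fold change of -1.31 with a standard error of 0.17 (limma, adjusted p = 0.00324). Zmpste24 fell by 1.21 ± 0.15 (SE; limma, adjusted p = 0.00283). Rcn2, a calcium-binding protein of the endoplasmic reticulum, fell by 0.92, and Skp2, the ubiquitin ligase subunit that promotes entry into S phase, fell by 0.74. The probe set of Mir145a fell by 1.04. Vps26c, Selenon, Ltbp1, Cdk19, Spns1, Arrdc4 and Aacs, which encodes acetoacetyl-CoA synthetase, fell by 0.67 to 0.73. Limma's adjusted p of these genes was at most 0.0369. The calls of Ltbp1, Cdk19 and Spns1 ended in at least 1 fit with a single array left out, with adjusted p of up to 0.0894, 0.138 and 0.109 (limma).

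Dpt, which encodes the matrix protein dermatopontin, rose most with the mimic, from 4.41 ± 0.02 to 5.66 ± 0.26 (log2, SD, n = 3), a log2 fold change of 1.25 ± 0.10 (SE; limma, adjusted p = 0.000444). The nuclear receptor gene Nr4a1 rose by 1.10 and Itgbl1 by 0.85. Fhl2 (0.81), Ccn2 (0.76), Id1 (0.67) and Thbs1 (0.66), which encodes thrombospondin 1, also rose, as did Tcp11l2 (0.70), Asah1 (0.70), Calcrl (0.66), Aspn (0.63) and Mob3a (0.62). The largest adjusted p among these rises was 0.0266 (limma, Aspn), and the call of Aspn alone ended with single arrays left out (limma, adjusted p of up to 0.126).

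Cell division and sterol genes were lower with the mimic. Of 24 mitosis genes tested, 17 fell, and 23 did so adjusted over the list alone, with a median log2 fold change of -0.40 (camera, adjusted p = 1.54e-23, and adjusted p = 0.0967 with an estimated correlation). Mki67, a marker of cycling cells, fell by 0.63, Cenpf by 0.59, Bub1b by 0.53 and Kif20a by 0.51 (limma, adjusted p of at most 0.0206). Of 28 DNA replication genes, 8 fell, and 17 did so adjusted over the list alone, with a median of -0.21 (camera, adjusted p = 1.28e-12, and adjusted p = 0.214 with an estimated correlation). Mcm3, Mcm5 and Mcm6, subunits of the replicative helicase, fell by 0.57, 0.49 and 0.41, and Uhrf1 fell by 0.49. Of 20 sterol synthesis and uptake genes, 9 fell, and 19 did so adjusted over the list alone, with a median of -0.30 (camera, adjusted p = 3.31e-16, and adjusted p = 0.0967 with an estimated correlation). Idi1 fell by 0.51, Sqle by 0.41, and Mvk and Stard4 by 0.39 each. Each mimic array lay below the controls in the 3 lists, and mimic 3 lay lowest, with list medians of -0.51 for mitosis, -0.34 for replication and -0.38 for sterol genes against the control mean.

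The other lists held fewer changes with the mimic. Of 28 matrix and myofibroblast genes, Ccn2, Thbs1 and Lum rose, and 4 rose adjusted over the list alone, with a median of 0.01 (camera, adjusted p = 0.0246, and adjusted p = 0.779 with an estimated correlation). This list's call also ended without mimic 1 (camera, adjusted p = 0.118) and without mimic 2 (adjusted p = 0.0832, with a median of -0.001). Of 17 fatty acid synthesis and adipocyte genes, Me1, Elovl6, Acly and Plin2 fell by 0.53, 0.47, 0.32 and 0.25. Adjusted over the list alone 7 fell and 1 rose. The list pointed down but did not pass the threshold (camera, unadjusted p = 0.0354, adjusted p = 0.1). Of 23 immediate early genes, Nr4a1 and Klf4 (0.43) rose, and Zfp36 (-0.61), Ier2 (-0.45) and Fos (-0.37) fell, with 4 rises and 3 falls adjusted over the list alone (camera, adjusted p = 0.0897). Single calls were the falls of Ago1 (-0.42) among the small RNA genes (camera, adjusted p = 0.143), Ccl7 (-0.31) among inflammatory genes (0.686), Echs1 (-0.25) in fatty acid oxidation (0.686) and Cox4i1 (-0.21) in the respiratory chain (0.436), the rise of Dnajb9 (0.53) among stress genes (0.421), and falls of Tnfrsf10b (-0.31) and Phlda3 (-0.21) among p53 targets (0.424). Adjusted over the list alone, 2 small RNA genes fell, 1 p53 target rose and 3 fell, and no respiratory chain gene was called (limma, 4 with an unadjusted p under 0.05), while the counts of the other 3 lists stayed at 1. The adjusted camera p was 0.783 for interferon-stimulated genes, 0.581 for glycolysis and hypoxia genes, 0.222 for ribosomal proteins and 0.686 for markers of other cell types. Limma called no member of these 4 lists, of which 2, 3, 2 and 1 members had an unadjusted p under 0.05. In fatty acid oxidation the median was -0.01 where the mean was 0.01 and camera pointed up, and in the inflammatory list the median was 0.02 where the mean was -0.03 and camera pointed down. For markers of other cell types the median was 0.00 where the mean was -0.03 and camera pointed down.

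Of 16 reported miR-378 targets tested, Casp9, an initiator caspase, fell by 0.21 with the mimic (limma, adjusted p = 0.0254), also adjusted over the list alone, and held in 3 of the 9 fits with an array left out. The list as a whole did not pass the threshold with the mimic (median -0.05, camera, adjusted p = 0.525). It holds reported targets of either arm of miR-378, so this does not speak for targets of miR-378-3p alone. Log2 fold changes with the mimic were 0.08 for Crat, -0.01 for Med13, -0.10 for Tob2, -0.17 for Igf1r, 0.13 for Grb2, -0.08 for Gli3, -0.08 for Sufu, -0.13 for Npnt, 0.14 for Pdk1, 0.02 for Atg12, -0.09 for Pik3ca, -0.03 for Gabpa, -0.00 for Ksr1, 0.07 for Galnt7 and -0.15 for Vegfa, none past the threshold (limma). With the inhibitor, Vegfa rose by 0.76 and Galnt7 by 0.36, and 5 members rose adjusted over the list alone (median 0.06, camera, adjusted p = 0.137). Ppargc1b, whose intron holds the miR-378 hairpin, stood near the level filter in each group, at 3.92 ± 0.03 in the controls, 3.95 ± 0.05 with the mimic and 3.97 ± 0.05 with the inhibitor (log2, SD, n = 3). It was not called in either comparison (limma, adjusted p = 0.816 and 0.559).

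In all, 425 of 11963 genes changed with the mimic (3.55%), of which 132 rose and 293 fell (limma), and 13 of the rises and 23 of the falls reached 1.5-fold. The groups did not overlap in 21.3% of all genes tested, against 10% by chance. After quantile normalization of the arrays 335 genes rose and 439 fell, and without mimic 3 the split was 300 rises to 282 falls. The count was 133, 171 or 141 without control 1, 2 or 3, and 188 without mimic 1. Of the mimic calls of named genes, those of Phlda3 and Plin2 held in 1 of the 9 fits with an array left out, those of Ccnb2, Cox4i1, Echs1, Lrrc17 and Sfrp2 in 2, and those of Casp9, Cdk19, Narf, Tnfrsf10b and Zswim4 in 3 (limma). Those of Ago1, Ccng2, Eif3k, Elovl6, Gpr137b, Mxd4, Rras, Sc5d and Uhrf1 held in 4, those of Acly, Aspn, Bub1b, Dtl, Gja1, Klf4, Ltbp1, Mcm6 and Spns1 in 5, those of Ccl7, Dnajb9, Eno2, Hbegf, Me1 and Nrn1 in 6, that of Idi1 in 7 and that of Bmf in 8.

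The second question was which transcripts rise when miR-378-3p is blocked. The only control was the RISC-free siRNA, with no mimic or inhibitor of another sequence. Responses to the mimic or inhibitor unrelated to miR-378-3p thus cannot be told apart from effects of this microRNA. With the inhibitor, Ereg (gene ID 13874), which encodes the epidermal growth factor receptor ligand epiregulin, rose most, and went from 4.22 ± 0.03 to 6.15 ± 0.20 (log2, SD, n = 3), a log2 fold change of 1.93 ± 0.10 (SE; limma, adjusted p = 7.67e-06). Hbegf, another ligand of that receptor, rose by 1.17, Inhba, a subunit of activin, by 1.21, Myc by 1.16 and Ccnd1, which encodes cyclin D1, by 1.14. The cationic amino acid transporter gene Slc7a1 rose by 1.29, Nr4a1 by 1.25, Klf4 by 1.19, Flvcr1 by 1.16, Ero1a by 1.12, Ptgs2, which encodes cyclooxygenase 2, by 1.09 and Efnb2 by 1.07. Limma's adjusted p was at most 0.000369 for these 12 genes.

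Mir145a (-1.07) and Lrrc17 fell most with the inhibitor. Lrrc17 went from 8.16 ± 0.06 to 7.12 ± 0.07 (log2, SD, n = 3), and so fell by 1.04 ± 0.05 (SE; limma, adjusted p = 7.67e-06). The proteoglycan genes Aspn and Lum fell by 0.83 and 0.66, Sfrp2, a secreted Wnt regulator, by 0.73, the basement membrane gene Nid2 by 0.70 and Apod by 0.62. Trim30a fell by 0.85, Prokr1 by 0.78, Ccl5 by 0.65, and the cell death gene Bmf and Ypel3 by 0.62 each (limma, adjusted p of at most 0.00547).

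DNA replication and p53 target genes were higher with the inhibitor. Of 28 replication genes, 22 rose, and 23 did so adjusted over the list alone, with a median of 0.31 (camera, adjusted p = 2.64e-11, and adjusted p = 0.122 with an estimated correlation). Ccne1, which encodes cyclin E1, rose by 0.65, Cdt1 and Chaf1b by 0.54 each and Mcm3 by 0.52. Of 21 p53 targets, 14 rose and 1 fell, against 14 rises and 2 falls adjusted over the list alone, with a median of 0.40 (camera, adjusted p = 2.02e-07, and adjusted p = 0.122 with an estimated correlation). Mdm2, the ubiquitin ligase of p53, rose by 0.95, Ccng1 by 0.87, Trp53inp1 by 0.79 and Eda2r by 0.72. Each inhibitor array lay above the controls in both lists, and inhibitor 1 lay highest, at 0.44 for replication genes and 0.50 for p53 targets.

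Of 31 interferon-stimulated genes on the array, only 15 passed the level filter, so the list result covers these alone. As a list they were lower, with 5 of 15 falling, 10 adjusted over the list alone, and a median of -0.20 (camera, adjusted p = 2.19e-06, and adjusted p = 0.0672 with an estimated correlation). Besides Trim30a and Ccl5, Stat2 fell by 0.35 and Irf9 by 0.29. Ribosomal protein genes fell as a list, with 6 of 24 members called, also 6 adjusted over the list alone, and a median of -0.12 (camera, adjusted p = 3.3e-07, and adjusted p = 0.0492 with an estimated correlation). Rps9, Rps20, Rpl24 and Rps15 fell by 0.26, 0.24, 0.22 and 0.18, on probe sets that may also read processed pseudogenes. Respiratory chain genes fell as a list by a median of 0.10 (camera, adjusted p = 5.01e-06, and adjusted p = 0.0203 with an estimated correlation). Of its 44 members 4 fell, among them Ndufs8 (-0.34), Cox8a (-0.26) and Cox4i1 (-0.26), and Ndufa9 rose by 0.49, against 3 falls and 1 rise adjusted over the list alone. Inflammatory genes rose as a list, by a median of 0.14 with 5 of 14 members called, also 5 adjusted over the list alone (camera, adjusted p = 0.000904, and adjusted p = 0.0492 with an estimated correlation). Csf1 rose by 0.68, and the chemokine genes Ccl2 and Ccl7 rose by 0.60 and 0.35.

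Of 23 unfolded protein and amino acid stress genes, 6 rose, also 6 adjusted over the list alone, among them Trib3 (0.66), Slc7a11 (0.55), Hyou1 (0.49) and the chaperone gene Hspa5 (0.43), with a list median of 0.15 (camera, adjusted p = 0.00222, and adjusted p = 0.346 with an estimated correlation). Of 23 immediate early genes, 12 rose and 3 fell, against 12 and 4 adjusted over the list alone, with a median of 0.24 (camera, adjusted p = 0.0144, and adjusted p = 0.367 with an estimated correlation). Fosl1 rose by 0.83, while Fos fell by 0.43. In fatty acid oxidation 1 of 22 genes, Echs1, fell by 0.24, also adjusted over the list alone, with a median of -0.08 (camera, adjusted p = 0.0181, and adjusted p = 0.424 with an estimated correlation). The last pair of lists lost their calls without inhibitor 2 (camera, adjusted p = 0.0621 for immediate early genes and 0.0553 for fatty acid oxidation).

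The remaining lists did not pass with the inhibitor. In the glycolysis and hypoxia list 4 of 16 rose, also 4 adjusted over the list alone, among them Hk2 (0.89), Slc2a1 (0.48) and Pfkp (0.17), and 3 of 15 small RNA genes rose, also 3 adjusted over the list alone, namely Xpo5, Ago2 (0.37 each) and Ran (0.27). Camera's adjusted p was 0.0685 and 0.0693. Among mitosis genes Ccnb2 fell by 0.34 (camera, adjusted p = 0.436), among sterol genes Sc5d rose by 0.27 (0.953), and among adipocyte genes Cebpb rose by 0.43 (0.304), each also the single call adjusted over the list alone. Of 28 matrix genes 4 rose, with Ccn2 (1.05), Thbs1 (0.90) and Tnc (0.72) first, and 3 fell, with Lum first, against 4 and 6 adjusted over the list alone (camera, adjusted p = 0.304). Median and mean lay above 0 in the mitosis (0.02 and 0.01) and sterol lists (0.02 and 0.03) where camera pointed down, and the matrix list had a median of -0.02 and a mean of 0.03. Limma called no marker of other cell types (6 tested, 0 with an unadjusted p under 0.05, camera, adjusted p = 0.41).

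In all, 1780 genes changed with the inhibitor (14.88%), of which 1330 rose and 450 fell (limma), and 175 of the rises and 16 of the falls reached 1.5-fold. The groups did not overlap in 37.7% of all genes tested, against 10% by chance. After quantile normalization 1269 genes rose and 1022 fell. The count was 974, 1051 or 990 without control 1, 2 or 3, 2790 without mimic 3, 1096 without inhibitor 1 and 1040 without inhibitor 3. Of the inhibitor calls of named genes, those of Cox8a, Pfkp and Rps15 held in 2 of the 9 fits with an array left out, that of Rpl24 in 3, and those of Ago2, Cebpb, Galnt7, Itgbl1, Mob3a and Uhrf1 in 4 (limma). Those of Narf, Rps9 and Sc5d held in 5, those of Echs1, Hyou1, Ndufs8, Ran, Rps20, Skp2 and Xpo5 in 6, and those of Irf9 and Stat2 in 7.

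**Figure D1:**
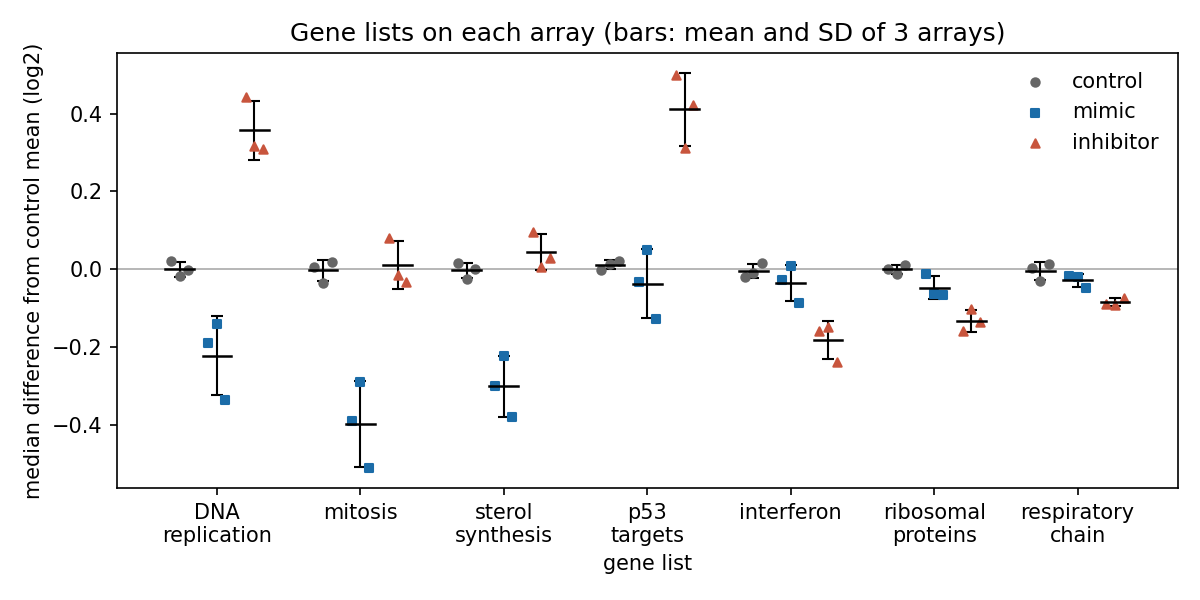
Median over the members of 7 gene lists of the difference from the control mean (log2), for each array, with circles for control, squares for mimic and triangles for inhibitor, and bars for the mean and SD of 3 arrays. Replication genes lay at -0.22 ± 0.10 with the mimic and 0.36 ± 0.08 with the inhibitor, and p53 targets at -0.04 ± 0.09 and 0.41 ± 0.09.

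Mimic and inhibitor were also compared directly, which leaves the control levels out of the difference. Replication genes were lower with the mimic, with 27 of 28 past the threshold, also 27 adjusted over the list alone, and a median of -0.56 (camera, adjusted p = 1.75e-15, and adjusted p = 0.12 with an estimated correlation). So were mitosis genes, with 22 of 24 lower, also 22 adjusted over the list alone, and a median of -0.42 (camera, adjusted p = 1.34e-08, and adjusted p = 0.141 with an estimated correlation), and sterol genes, with 13 of 20 lower, 15 adjusted over the list alone, and a median of -0.32 (camera, adjusted p = 9.1e-07, and adjusted p = 0.141 with an estimated correlation). Of 21 p53 targets 15 were lower and 2 higher with the mimic, against 16 and 2 adjusted over the list alone (median -0.48, camera, adjusted p = 3.7e-06, and adjusted p = 0.141 with an estimated correlation). Of 15 interferon-stimulated genes 7 were higher and 1 lower, against 8 and 1 adjusted over the list alone (median 0.21, camera, adjusted p = 0.000154, and adjusted p = 0.12 with an estimated correlation).

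Among the single genes, Nid1 and Gpr137b stood lower with the mimic than with the inhibitor, with log2 differences of -1.26 and -1.42, and Gja1, which encodes connexin 43, stood 2.82-fold lower (limma, adjusted p of at most 5.27e-05), while Aspn and Lum stood higher by 1.46 and 1.11 (limma, adjusted p of at most 6.47e-05). Stress, inflammatory and small RNA genes were lower with the mimic as lists (medians -0.21, -0.16 and -0.25, camera, adjusted p = 0.0022, 0.00496 and 0.0148), and respiratory chain, ribosomal and fatty acid oxidation genes higher (medians 0.07, 0.09 and 0.08, camera, adjusted p = 0.00265, 0.000797 and 0.0327). With an estimated correlation these 6 lists had adjusted p = 0.248, 0.12, 0.416, 0.12, 0.12 and 0.416 with an estimated correlation, in that order. The fatty acid oxidation call also ended with no level filter (camera, adjusted p = 0.146), without mimic 2 (camera, adjusted p = 0.1) and without inhibitor 2 (0.0583), and the small RNA call without both mimic 3 and inhibitor 1 (0.0708). Glycolysis and hypoxia genes (camera, adjusted p = 0.0533), reported targets, adipocyte, matrix and immediate early genes (0.0683 each) and markers of other cell types (0.709) did not pass, and in the matrix list the median was -0.01 where the mean was 0.04 and camera pointed up. For other cell types the median was 0.00 and the mean -0.02 where camera pointed up. In all 3204 genes differed (26.78%), 827 higher and 2377 lower with the mimic (limma), against 1670 and 2028 after quantile normalization.

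A transcript repressed by the microRNA would be lower with the mimic and higher with the inhibitor, and 48 genes fell with the mimic and rose with the inhibitor (limma). Among them were the basement membrane gene Nid1 (-0.58 and 0.68), Gpr137b (-0.58 and 0.84), Psrc1 (-0.55 and 0.56), Dtl (-0.53 and 0.59), Gja1 (-0.51 and 0.99), Cyb5r1 (-0.48 and 0.50) and Cdca7 (-0.46 and 0.40), besides Mcm3, Mcm5 and Mcm6. Another 23 genes rose with the mimic and fell with the inhibitor, among them Aspn, Lum, Itgbl1, Tcp11l2, Ifi27 (0.44 and -0.57), Vkorc1 (0.49 and -0.42), Pdgfrl (0.37 and -0.40), Mxd4 (0.35 and -0.39), Rras (0.33 and -0.51) and H2bc4 (0.37 and -0.39), whose probe set may also read other histone genes. Of the genes that fell most with the mimic, Dazap2 (-0.02) and Rcn2 (0.01) were not called with the inhibitor, nor was Zmpste24 (0.37, limma, adjusted p = 0.129), while Skp2 rose by 0.35 (limma, adjusted p = 0.0137).

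In addition 35 genes fell and 46 rose with both RNAs. Mir145a, the repressor of inflammatory mRNAs Zfp36 (-0.61 and -0.60), Bmf (-0.42 and -0.62), Eno2 (-0.41 and -0.41), Ccng2 (-0.39 and -0.41), Hddc3, Fos, Narf, Sfrp2 and Eif3k fell, and Nr4a1, Ccn2 (0.76 and 1.05), Thbs1 (0.66 and 0.90), Asah1, Fhl2, Nrn1 (0.55 and 0.54), Errfi1 (0.53 and 0.59), Trib2, Zswim4 and Id1 rose. Unchanged groups set against the same controls gave 0 genes in each of the 4 combinations in 100 simulations. Such data hold no changed gene and give few calls at all, so these counts of 0 are no baseline for the observed ones. Independent lists would share 32.6 (fell, then rose), 5.0 (rose, then fell), 11.0 (fell in both) and 14.7 genes (rose in both). These numbers depend on the level filter. With the filter at the 60th percentile, 285 of 7976 genes fell with the mimic, 1317 rose with the inhibitor and 48 did both. The overlap of independent lists was not computed there, so 48 against 32.6 is no evidence of an excess. Across genes, which are not independent replicates, the correlation of the fold changes was -0.05 against 0.50 in the simulation, and their covariance was -0.00135 against 0.00343, a difference of -0.00478. With 3 control arrays no split into 2 groups of at least 2 was possible, so part of the excess of genes changed the same way can come from the shared controls. The count of 48 was 9, 8 or 10 without control 1, 2 or 3, 14 without mimic 1, 94 without mimic 2 and 21 without inhibitor 3.

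**Figure D2:**
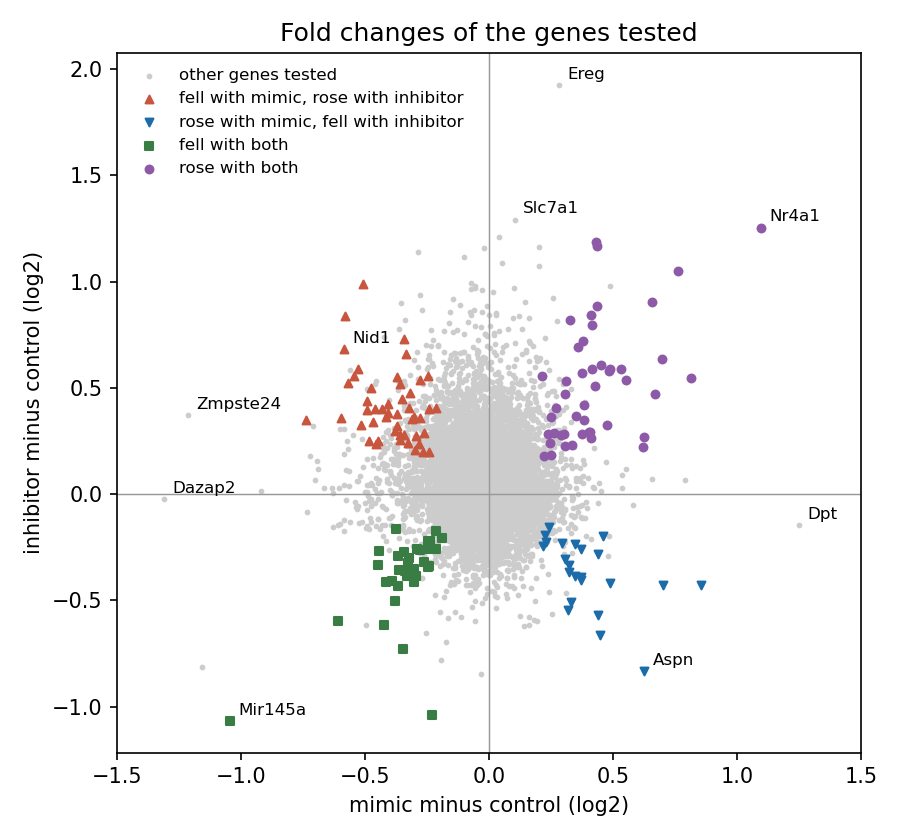
Log2 fold change with the mimic (horizontal axis) and with the inhibitor (vertical axis), each against the control, for 11963 genes, with genes past the threshold in both comparisons marked by shape and colour. The marked genes number 48 (fell, then rose), 23 (rose, then fell), 35 (fell in both) and 46 (rose in both).

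**Figure D3:**
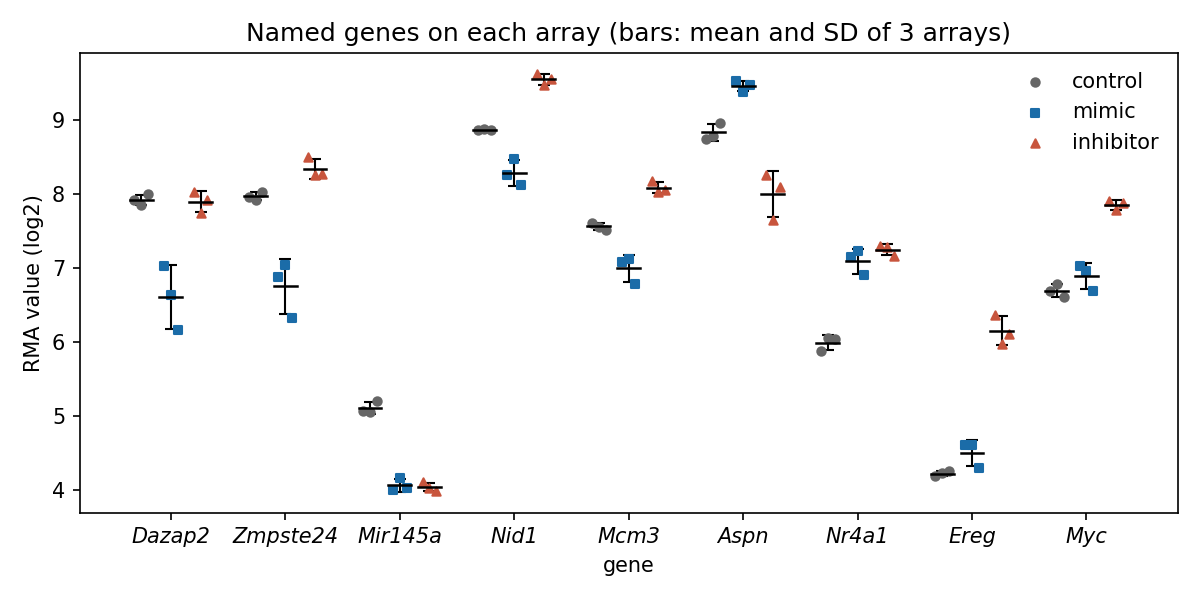
RMA value (log2) of 9 named genes on each array, with circles for control, squares for mimic and triangles for inhibitor, and bars for the mean and SD of 3 arrays. Dazap2 fell with the mimic to 6.61 ± 0.43, Mir145a fell with both RNAs to 4.07 ± 0.09 and 4.04 ± 0.06, and Ereg rose with the inhibitor to 6.15 ± 0.20.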

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

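Tests of the growth state of single cultures, of an odd control array and of the control RNA, and both changed settings for the replication list with either correlation, were chosen after the results were seen.

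Probe sets outside the gene tests also carried signal. Of 824 tested probe sets that list several genes, 7 rose with the mimic and 80 with the inhibitor (limma), and 92 and 149 fell. Many list the same genes, and these falls stand for 28 and 59 distinct gene listings and the rises for 5 and 44. Of 2079 tested probe sets with no gene listed, 1 rose with the mimic and 19 with the inhibitor, and 1 and 8 fell. Of 26 probe sets that list only histone genes, 24 fell with the mimic, with a median log2 fold change of -0.30, and 10 rose with the inhibitor, with a median of 0.14. Single histone genes cannot be read from them.

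DNA replication genes lay lower with the mimic and higher with the inhibitor, as a list with adjusted p = 0.214 and 0.122 with an estimated correlation (camera). A wider or narrower spread of values on some arrays was argued against, since after quantile normalization the list median stayed at -0.188 with the mimic and 0.258 with the inhibitor (camera, adjusted p = 3.81e-12 and 2.18e-10, and adjusted p = 0.00184 and 0.00762 with an estimated correlation). The arrays mimic 3 and inhibitor 1 alone were argued against too, since without both the medians were -0.181 and 0.267 (camera, adjusted p = 2.99e-11 and 4.89e-10, and adjusted p = 0.0842 and 0.0987 with an estimated correlation). The growth state of single cultures stays open: the first axis of deviations within groups, with 60.2% of that variance, correlated with the inhibitor-minus-mimic fold change at r = 0.478 across genes, where unstructured deviations reached at most 0.039 and quantile normalization left 0.41. On this axis mimic 3 (-13.92) and mimic 2 (10.24) lay apart as did inhibitor 1 (8.75) and inhibitor 2 (-6.72), and 27 of 28 replication genes loaded on one side. The share of all genes tested on that side was not counted, so the axis cannot be assigned to growth. A difference in density or growth between dishes may share in the pattern, and an effect of miR-378-3p on growth remains a hypothesis.

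The 35 genes that fell and the 46 that rose with both RNAs included Mir145a and Nr4a1. Fits without control 1, 2 or 3 called 24, 37 and 26 genes the same way. At least 0.5 times both log2 fold changes against the held-out control alone was shown by 95.8%, 94.6% and 92.3% of them. This argued against 1 odd control array for the genes called in those fits. Genes no longer called without a control were not tested in this way. Over all genes tested the controls had a root mean square deviation from their mean of 0.0545 to 0.0583, against 0.0603 to 0.1335 for the other arrays. For genes changed the same way, an effect of the control RNA cannot be told apart from a response to both RNAs unrelated to miR-378-3p. This is because the design holds 0 untransfected arrays.

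Chance was weighed by other splits of the arrays. The splits of 6 arrays are too few for a share under 0.05: 1 of 10 splits, the real one, gave as many genes in each comparison, with 425 genes for the mimic, 1780 for the inhibitor and 3204 between them, and at most 0 in any other split. For the genes that fell with the mimic and rose with the inhibitor, the real assignment of the 9 arrays gave 48, and the highest of 99 others gave 0. Only 1 of those others called enough genes in both comparisons to reach 48, too few for a share under 0.05. Independent lists would share 32.6, a number that depends on the level filter.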

How the results depend on the processing

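The fit without mimic 3 and inhibitor 1, and scaling of the arrays for gene lists, were chosen after seeing the data. No call of a list or a named gene turned direction under any alternative run. Of 182 calls of named genes, 122 held under every alternative run for them, among these Dazap2, Zmpste24, Dpt and Ereg, and 149 held after median centring. The fold of at least 1.5 was not among the alternatives run for named genes. Of 24 list calls, 3 held with an estimated correlation, 24 held under quantile normalization and median centring, and 21 to 24 held with 1 array left out.

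The count of genes changed by the mimic, 425, was 774 after quantile normalization, 231 after median centring, 248 with only the 6 arrays compared and 911 without mimic 3 and inhibitor 1, and ranged from 133 to 582 with 1 array left out. The inhibitor's count of 1780 ranged from 974 to 2790. A fold of at least 1.5 left 36, 191 and 410 genes for the mimic, the inhibitor and their difference, by construction. The 48 genes that fell with the mimic and rose with the inhibitor became 77 after quantile normalization, 18 after median centring, 88 without mimic 3 and inhibitor 1, 8 to 94 with 1 array left out, and 0 at a 1.5-fold change (limma, also 0 at an unadjusted p under 0.05). Fewer arrays carry less power, which cannot account for the counts that grew. Mimic 3 has no part in the inhibitor's fold changes, so leaving it out, with 2790 calls, acted only through the estimate of the spread. With only the 6 arrays compared the inhibitor's count was 2569. The cause of the other counts that grew was not tested.

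List calls for the mimic, 4 of 17, became 7 with no level filter and 0 with an estimated correlation (3 at an unadjusted p under 0.05). They went from 9 to 3 for the inhibitor and from 11 to 0 (5 unadjusted) between mimic and inhibitor with an estimated correlation.

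With the replicate number as a block, 289, 1575 and 3028 genes changed and 26 fell with the mimic and rose with the inhibitor, and no list call moved. Deviations of arrays with the same number correlated at -0.589 to 0.224, and not every array correlated best with its own number. Whether arrays of the same number share a day or batch is not given in the labels, and these correlations cannot settle it. Seed site, heptamer and other microRNA alternatives were not run. Signal near the level filter of 3.86, as for Ppargc1b, limits what could be read.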

Other observations

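The test of release by the inhibitor was chosen after the result was seen.

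Mir143 lies beside Mir145a and both microRNAs are processed from 1 primary transcript. Its probe set, chosen after its values were seen, fell like that of Mir145a, from 4.62 ± 0.06 in the controls to 4.25 ± 0.04 with the mimic and 4.33 ± 0.05 with the inhibitor (log2, SD, n = 3), by 0.37 and 0.29 (limma, adjusted p = 0.00447 and 0.00455). The Mir378a probe set, also chosen after its values were seen, stood at 3.86 ± 0.11 in the controls, 3.95 ± 0.03 with the mimic and 3.98 ± 0.05 with the inhibitor, and was not called (limma, adjusted p = 0.521 and 0.213). Whether these probe sets read a mature, precursor or primary form is not given in the sources used here.

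One hypothesis was that genes with the largest falls under the mimic are held down by the cells' own miR-378-3p, so that the inhibitor would release them. Of 23 genes that fell at least 1.5-fold with the mimic, 2 rose with the inhibitor (8.7%, exact 95% interval 1.1 to 28), against 11.1% of the other 11940 genes tested, and 15 of the 23 had a positive log2 fold change with the inhibitor (median 0.03). Falls and rises were measured against the same 3 controls, which gave unchanged genes a correlation of 0.50 in simulation and so holds genes picked for a fall back from rising. With this and the width of the interval, release and no release cannot be told apart on these 23 genes. Of all 293 falls, 16.4% rose with the inhibitor. That share cannot be set against the 11.1%, because shares of calls depend on the level of the genes. With the level filter at the 60th percentile, 1317 of all 7976 genes tested rose with the inhibitor, and so did 48 of 285 falls. No share was computed for genes matched in level.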
